A study of Mus musculus with 6 samples.

How the data were processed

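Testis RNA of 6 mice was profiled on 1-colour Illumina bead arrays with biotin-labelled cRNA, 1 array per mouse. Total RNA was extracted with Qiagen RNeasy columns, checked on an Agilent Bioanalyser and amplified with the Illumina TotalPrep kit, per the labels' protocols. Genotype and litter were taken from the labels: WT, HET and KO had 2 mice each, and replicate numbers 1 and 2 stand for litters 1 and 2, each with 1 mouse per genotype. The 6 samples were separate mice, so p-values of single probes measure the spread between animals. Permutation p-values came from shuffling the changes of genes between lists, so they measure the spread over genes and not between animals.

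The authors' non-normalized table gave, per the file headers, the average signal of each probe as a linear intensity for 45281 probes. The deposited table also held a detection p-value for each probe on each array, per the file headers. GenomeStudio is the software named in the submitters' processing notes, and its version is not given in the sources used here. The deposited signals were not background-subtracted, with lowest values of 74.1 to 80.3 and array means of 340.7 to 390.3. The authors' series matrix held intensity values of the same arrays, and these were set against the non-normalized signals to learn their scale. Each array had been multiplied by 1 constant, from 0.960 to 1.10, to give a common mean of 374.5, with a largest difference of 0.105 that came from rounding. Those values were therefore linear, not centred per probe, and had medians of 94.3 to 105.4. The name of that scaling is not given in the sources used here.

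Signals were normalized with the neqc function of limma 3.58.1 in R 4.3.3. It fitted normal-exponential background parameters from the detection p-values, because the table held no control probes, added an offset of 16, applied quantile normalization and took log2. Probes with a detection p under 0.05 on at least 2 of the 6 arrays were kept, which left 22048 probes (48.7%). Between 19809 and 21323 probes were detected per array, and the number of arrays limits the precision of every value. Group means were fitted with lmFit over all 6 arrays, so that the 3 groups shared 1 estimate of the spread with 3 residual degrees of freedom, and eBayes added 6.49 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the probes tested in each comparison, and the threshold was an adjusted p of 0.05. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333 and was not used for single genes. A probe whose detection p exceeded 0.05 on both arrays of a group was treated as not above background there. Its fold is given as "at least", the brighter group's mean set against, per array, the higher of the lowest signal among detected probes and the probe's own value.

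Gene names came from the symbol column of the table and were updated through an annotation table of assembly GRCm38.p6, used for names and chromosomes. By symbol 22841 probes matched, by a synonym of a single gene 11981, while 188 symbols were synonyms of several genes and 10271 had no match and kept the name in the file. A further 27 symbols had been turned into dates and were left unnamed. Clone names matched by synonym can be out of date, and probe positions were not analysed here.

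Gene lists held 781 members in 23 lists: H3.3 genes and their chaperones, replication-coupled histone genes, histone variants, transition proteins and protamines, 4 germ cell stages, Sertoli cells, Leydig cells, peritubular myoid cells, leukocytes, endothelial cells, erythrocytes, epididymis, p53 targets and apoptosis, interferon-stimulated genes, proliferation, immediate early and heat shock genes, cholesterol biosynthesis, chromatin regulators, the piRNA pathway, and genes next to H3f3b on chromosome 11. They were tested with camera in limma (preset correlation 0.01) on 1 probe per gene, the probe with the highest mean, over 15481 genes, and adjusted over the 23 lists. X-linked and Y-linked genes formed a family of their own. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Some genes sit in more than 1 list, such as the protamines among the elongating spermatid genes.

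The genes named for each comparison were H3f3b and H3f3a, then the 12 largest positive and 12 largest negative changes among probes that passed and whose arrays did not overlap between the groups, with 1 probe per gene. Where fewer than 6 passed in a direction, the genes with the smallest p were added up to 6 as values that did not pass. From each list described, up to 4 members with the smallest p were named. The groups, comparisons, tests, gene lists, this rule and the alternatives were fixed before the data were examined. Added after the results were seen were the 7 tests of explanations and a scan of 187 gene families, each with at least 8 tested genes that share the stem of their symbol. A first version of that scan, with looser stems, held 201 families.

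The alternatives were no background correction, normexp with offset 50, cyclic loess, median scaling, the series matrix values, no filter, a detection p under 0.01 on all 6 arrays, litter as a block, a fit of only the 2 groups compared, an intensity trend with robust variance, 1 probe per gene, and leaving out each array in turn. Pairing by litter comes from the labels. Deviations of same-litter arrays from their group means correlated at 0.0832 between WT and HET, 0.122 between WT and KO and 0.158 between HET and KO, across probes.

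The steps were tested on simulated data drawn from the real means and spreads. For KO against WT over 22048 probes, 2.39% of probes changed by 0.5 on the log2 scale were recovered, 66.3% of those changed by 1 and 99.4% of those changed by 2, with 36 false calls over 5 simulations. For KO against HET the shares were 3.28%, 66.9% and 99.1%, with 22 false calls, and for HET against WT, simulated without a change, there were 0 false calls. Over 15481 genes, a list shifted by 0.4 was called in 10 of 10 simulations and unshifted lists in 0 of 210. These simulations drew each gene independently, whereas estimated correlations in the data reached 0.269, for the leukocyte list. The 0 of 210 therefore does not cover false calls of lists whose genes move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.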

Results

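Gene expression was measured in the testis of mice with both, 1 or neither copy of H3f3b intact. H3f3b is 1 of 2 mouse genes, with H3f3a, that encode the replacement histone H3.3. The knockout allele was made by deleting a floxed H3f3b allele with Zp3-Cre, a recombinase expressed in growing oocytes. There were 3 groups of 2 mice, wild type (WT), heterozygous (HET) and homozygous knockout (KO), and each of 2 litters gave 1 mouse of each genotype. The labels describe the mice as 8 weeks old in 1 field and as embryos in another, and the age of 8 weeks, also stated in the design, is used here. Each array carried 45281 probes, of which 20188 and 19809 were detected in WT, 20707 and 20349 in HET, and 21323 and 20682 in KO. With 2 arrays per group, the number of arrays limits the precision of every value.

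H3f3b itself was read first, in every sample. Its probe gave log2 values of 11.79 and 11.73 in WT, 11.10 and 10.96 in HET, and 4.43 and 4.29 in KO, where the detection p-values of 0.174 and 0.561 did not exceed background. On the linear scale the mean was 3445 ± 96.2 in WT and 2078 ± 142 in HET (SD, n = 2), so HET held 60.3% of the WT level, with 62.0% and 58.6% within the 2 litters. In KO, H3f3b fell at least 142-fold against WT (log2 change -7.40, SE 0.14, limma adjusted p = 1.02e-08) and at least 85.8-fold against HET (-6.67, SE 0.14, adjusted p = 2.7e-08). The HET change of -0.73 (SE 0.14) did not pass (adjusted p = 0.484), although it was below WT in both litters; with the series matrix values it passed (adjusted p = 0.0018), as did the H3f3b level with normexp with offset 50 (adjusted p = 0.0266; range over all settings 0.0018 to 0.806). A dimmer H3f3b probe, listed as 9430068D06Rik, was not above background in HET and KO and fell at least 1.29-fold in KO (adjusted p = 0.0435), a call lost in each of the 4 fits without 1 array in which it was tested, to an adjusted p of 0.156 without KO replicate 1. The 3 probes of H3f3a differed between KO and WT by 0.04, 0.10 and -0.07 (adjusted p = 0.87, 0.752 and 0.801). The direction of each of these 3 small differences turned under some other settings. Where the probes lie relative to the deleted part of H3f3b was not analysed here.

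**Figure D1:**
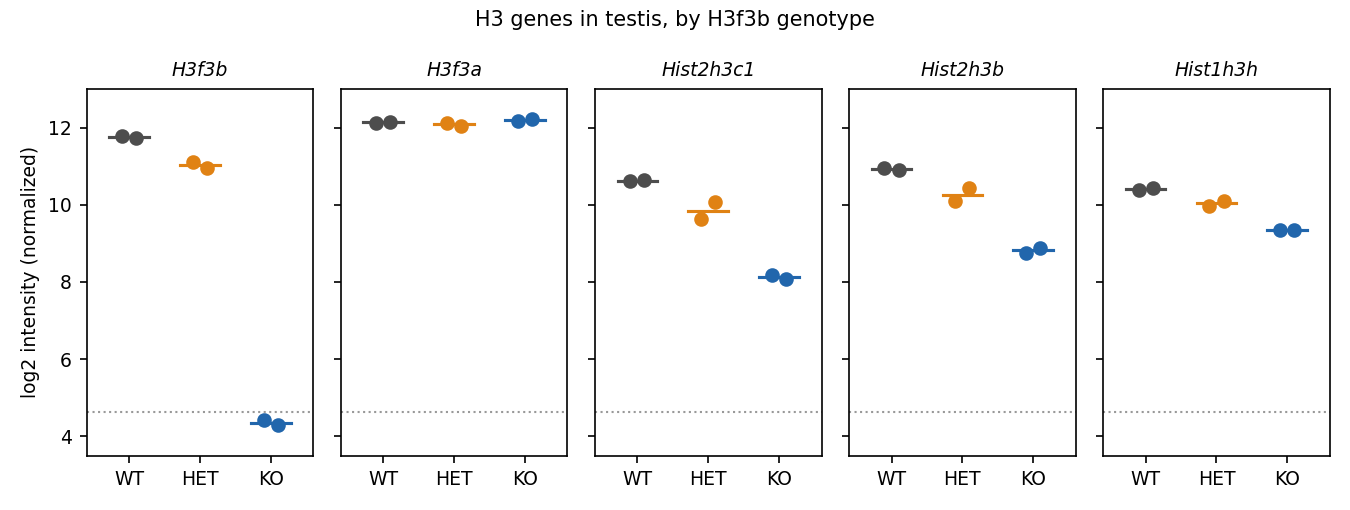
Normalized log2 intensity (vertical axis) of H3f3b, H3f3a and 3 replication-coupled H3 genes in the WT, HET and KO mice; points are single mice, bars are group means and the dotted line is the background floor at 4.64. H3f3b lay between 11.73 and 11.79 in WT and at 4.43 and 4.29 in KO, while Hist2h3c1 differed by -2.50, Hist2h3b by -2.11 and Hist1h3h by -1.07 between KO and WT.

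The central comparison asked what homozygous loss of H3f3b changed in the testis. After H3f3b, the largest decreases in KO against WT were in Ston1, an endocytic adaptor gene (array name 4921524J06Rik), which fell by 2.92 on the log2 scale (SE 0.131, adjusted p = 1.8e-05), and in the replication-coupled histone H3 genes Hist2h3c1 (now H3c14; -2.50, SE 0.167, adjusted p = 3.4e-04) and Hist2h3b (now H3c13; -2.11, SE 0.154, adjusted p = 5.3e-04). A second Ston1 probe differed by -2.68, whereas 2 other probes of Hist2h3c1 differed by -0.20 and 0.14. Galnt17, Hs3st3b1, Art1, Hspbap1, Rundc3a, Nudt12os and Palld fell by 1.55 to 1.73, with adjusted p from 0.00163 to 0.0112, but another Hs3st3b1 probe differed by only -0.40 and another Palld probe by -0.56. The largest increase was in Hsd3b4, of the 3-beta-hydroxysteroid dehydrogenase family, which rose by 2.14 (SE 0.173, adjusted p = 0.00114), and Akr1c19, an aldo-keto reductase gene, rose by 1.44 (SE 0.141, adjusted p = 0.0028). Further increases were in Lor, which encodes the cornified envelope protein loricrin (1.88, at least 3.10-fold, as WT was not above background), the transcription factor genes Snai2 (1.55) and Hoxa5 (1.42, at least 2.29-fold), the T cell kinase gene Lck (1.33), Ampd1 (1.60), the vomeronasal receptor gene Vmn1r181 (1.54) and Cited4 (1.21). Their adjusted p-values ran from 0.0028 to 0.0198. Cyth1 rose on 1 probe (1.45, adjusted p = 0.0175) and differed by -0.04 on its other probe. BC057079 rose by 1.92 (SE 0.134, adjusted p = 4.18e-04), and is 1 of 3 genes among these 24 with only a clone or model name, 2 higher and 1 lower.

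In all, 1174 of 22048 probes passed in KO against WT, 354 higher (336 genes) and 820 lower (739 genes), where 5579 had an unadjusted p under 0.05 against 1102 by chance. A change of at least 2-fold was seen for 32 of the higher and 127 of the lower probes, and the smallest change that passed was 0.54. With litter as a block 1470 passed (448 higher, 1022 lower), 1133 of them among the 1174. The direction of the split depended on the scaling: 1305 probes were higher and 1624 lower without background correction, 1296 and 1705 with normexp with offset 50, 1013 and 749 with median scaling, which moved the median of all probes to 0.11, and 2892 and 1332 with the series matrix values. The count also fell with any 1 array left out. Each such fit leaves 1 mouse in a group and fewer residual degrees of freedom. Leaving out a HET array, which is not in this comparison, lowered the count as well. The fall therefore mixes a loss of power with dependence on single arrays. Of the 24 genes named by size, 15 passed with any 1 array left out, among them H3f3b, Ston1, Hist2h3c1, Hist2h3b, Art1, Hspbap1, Rundc3a, Palld, Hsd3b4, Akr1c19, Lor and Snai2. Of the other 9, Ampd1 lost the call without either KO array and the rest both without WT replicate 2 and without KO replicate 1, with highest adjusted p-values of 0.0962 for Ampd1, 0.0776 for Cited4, 0.109 for Cyth1, 0.0911 for Galnt17, 0.0659 for Hoxa5, 0.0625 for Hs3st3b1, 0.0876 for Lck, 0.0569 for Nudt12os and 0.0733 for Vmn1r181.

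Genes of spermatids were lower in KO and genes of Sertoli cells, the somatic nurse cells of the seminiferous tubule, were higher. Of 38 round spermatid genes, 37 lay below 0, with a median of -0.46 (SD over genes 0.306); 9 fell over all probes and 21 when adjusted over the list alone. Catsper1, a sperm calcium channel gene, fell by 1.12 (adjusted p = 0.0112), Spata46 by 0.82 (0.0249), Spata25 by 0.73 (0.0339) and the spermatid transcription factor gene Crem by 0.69 (0.0331), although 3 other Crem probes differed by 0.15, -0.21 and 0.67. Of 37 elongating spermatid genes, 35 lay below 0 (median -0.26), and 2 fell, or 4 adjusted over the list alone. These were led by Tekt5, a flagellar tektin gene (-0.78, adjusted p = 0.024), and Ccin (-0.67, 0.0482), while Ropn1 (-0.63, 0.0575) and Fscn3 (-0.76, 0.0638) did not pass. Of 35 Sertoli cell genes, 33 lay above 0 (median 0.46, SD 0.234), and 8 rose, or 20 adjusted over the list alone. They included Espn (0.69, adjusted p = 0.0293; other probes 0.04, -0.42 and 0.25), the inhibin gene Inha (0.77, 0.0297), Clu (0.63, 0.0331) and the ligand gene Dhh (0.66, 0.0367). With camera, the round spermatid list passed at adjusted p = 1.53e-10, the elongating spermatid list at 3.04e-06 and the Sertoli cell list at 2.54e-08. None of the 3 calls held in camera with an estimated correlation (adjusted p = 0.297, 0.222 and 0.297). For the elongating spermatid list that correlation was -0.000371, below the preset 0.01. Its camera p still went from 3.97e-07 to 0.00966, so the loss there does not come from genes that move together. Each single gene named here that passed lost its call without at least 1 array, with highest adjusted p-values from 0.0852 for Catsper1 without WT replicate 2 to 0.187 for Ccin without KO replicate 2.

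**Figure D2:**
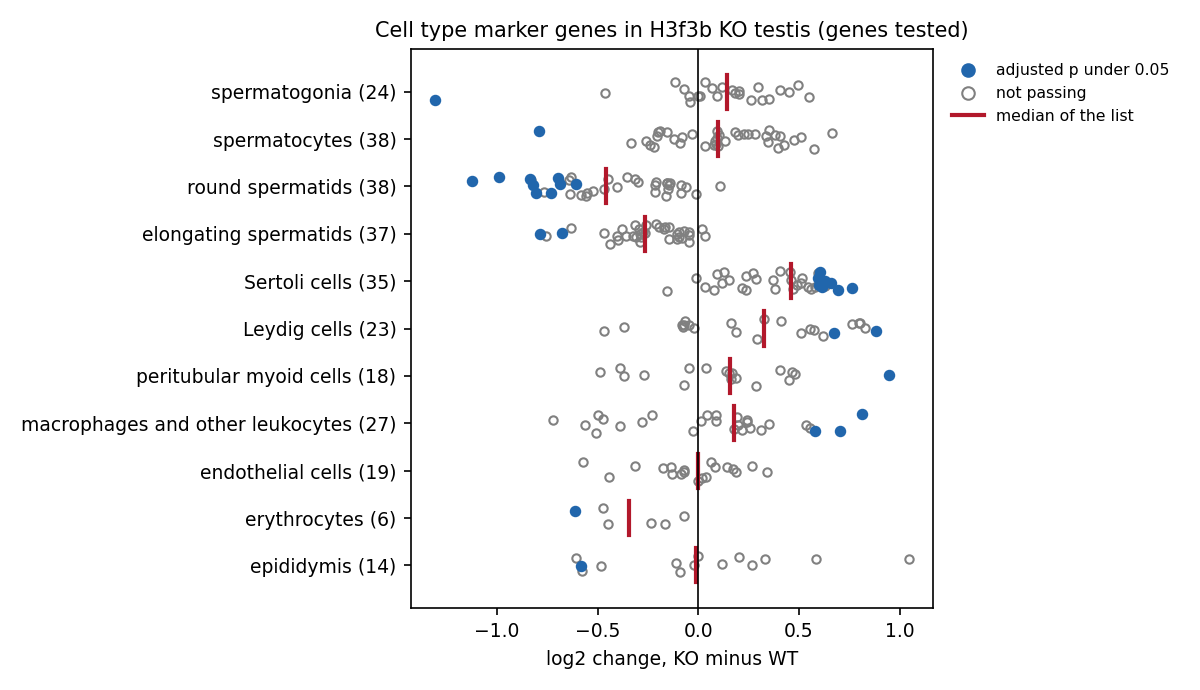
Log2 change in KO minus WT (horizontal axis) of the tested genes of 11 cell type lists (vertical axis, with the number of genes); filled points passed at an adjusted p under 0.05, open points did not, and red bars mark list medians. The medians were -0.46 for round spermatid, -0.26 for elongating spermatid, 0.46 for Sertoli cell and 0.33 for Leydig cell genes.

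Markers of the other cell types moved less evenly. Among 23 genes of the testosterone-producing Leydig cells the median was 0.33, with 2 higher over all probes and 9 higher and 1 lower adjusted over the list alone, and the list passed (camera adjusted p = 0.0175; adjusted p = 0.416 with an estimated correlation). Adh1 (0.88, adjusted p = 0.0322) and Vcam1 (0.67, 0.0326) rose, Timp2 (0.51, 0.0636) did not pass, and the steroid hydroxylase gene Cyp17a1 (0.76) passed with litter as a block (adjusted p = 0.0449) and not without it (0.0526). Genes of erythrocytes (6, median -0.34) were lower, with the carbonic anhydrase gene Car2 at -0.61 (0.0419) and the haemoglobin genes Hbb-b1 at -0.47 (0.134) and Hba-a1 at -0.45 (0.156). That list passed at adjusted p = 0.0419 (adjusted p = 0.369 with an estimated correlation) with 1 gene lower both over all probes and adjusted over the list alone, but not with litter as a block (0.0557), nor without WT replicate 1 (0.11), HET replicate 1 (0.0503) or KO replicate 1 (0.184). The lists of peritubular myoid cells (18 genes, median 0.16, adjusted p = 0.236), leukocytes (27, 0.18, 0.439), spermatogonia (24, 0.14, 0.281) and spermatocytes (38, 0.10, 0.236) did not pass. Single members did: Pdgfra (0.95, 0.018; another probe -0.10) among the myoid genes, Lyz1 (0.81, 0.0267; another probe -0.29), Fcgr3 (0.71, 0.0364) and Mrc1 (0.58, 0.0401) among the leukocyte genes, Lhx1 (-1.31, 0.0126) among the spermatogonial genes and the meiotic cohesin gene Rec8 (-0.79, 0.0426) among the spermatocyte genes. Adjusted over the list alone, 5 myoid genes were higher and 1 lower, 3 leukocyte genes higher and 2 lower, 1 spermatogonial gene lower and 0 spermatocyte genes changed. Endothelial genes (19, median -0.003, adjusted p = 0.561) and epididymal genes (14, -0.01, 0.561) had medians whose sign turned with median scaling and with the series matrix values. Nos3 (-0.57) passed with litter as a block (adjusted p = 0.0472) and not without it (0.0993), whereas the epididymal defensin gene Defb21 (-0.58) passed without the block (0.0494) and not with it (0.0515). Every single call in this group was lost without at least 1 array, with highest adjusted p-values from 0.0931 for Lhx1 without KO replicate 1 to 0.195 for Defb21 without WT replicate 2.

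Replication-coupled histone genes, which are expressed in S phase, were lower as a list in KO, with a median of -0.23 over 45 genes (camera adjusted p = 1.24e-04; adjusted p = 0.297 with an estimated correlation). The median was closer to 0 with median scaling (-0.15) and with the series matrix values (-0.08), and lowest with cyclic loess (-0.28). Of these 45, 8 fell over all probes and 12 adjusted over the list alone. The decrease lay in the H3 genes (9 genes, median -0.44, 3 passing) and H2B genes (11 genes, -0.45, 4 passing), with H4 genes at -0.18 (10 genes). H2A genes were mixed, with a median of 0.20 (13 genes, 6 below 0, 1 lower passing). These signs held under every scaling, but with median scaling the H2A median of 0.0826 lay below the 0.11 of all genes. Besides Hist2h3c1 and Hist2h3b, Hist1h3h (now H3c10) fell by 1.07 (SE 0.134, adjusted p = 0.00809; another probe -0.15) and Hist1h2bp (now H2bc22) by 0.70 (SE 0.135, adjusted p = 0.027). Both lost the call without 1 array, at highest adjusted p-values of 0.0793 without WT replicate 2 and 0.125 without KO replicate 1. In the same arrays, the spermatid lists were lower and the Sertoli cell list higher, as given above. Which forms of histone RNA the amplified cRNA represents was not analysed here. Of the 10 tested H3.3 genes and chaperones, only H3f3b changed, over all probes and adjusted over the list alone; Asf1a (0.24, adjusted p = 0.31), Hira (0.22, 0.393) and Daxx (-0.25, 0.37) did not pass, and the list median of -0.01, whose sign turned under 3 scalings, went with a mean of -0.74 set by H3f3b (camera adjusted p = 0.236). Histone variants (15 genes, median 0.10, adjusted p = 0.428), led by H2afv (0.48, 0.0842), and transition proteins and protamines (4 genes, -0.19, 0.224), led by Prm3 (-0.36, 0.154), had 0 members past the limma threshold over all probes and adjusted over the list alone. Probes of Prm1 and Tnp1 lie near the top of the signal range.

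Among the remaining lists, proliferation genes passed upward (31 genes, median 0.15, camera adjusted p = 0.0301; adjusted p = 0.297 with an estimated correlation), but not without WT replicate 2 (0.206) or KO replicate 2 (0.0535). With limma, 0 of these genes passed over all probes or adjusted over the list alone, with Mcm4 at 0.52 (adjusted p = 0.0572) and Mki67 at 0.57 (0.0932). Lists of p53 targets and apoptosis (30 genes, median 0.25, adjusted p = 0.0576), cholesterol biosynthesis (20, 0.26, 0.0741), chromatin regulators (41, 0.22, 0.173), immediate early and heat shock genes (21, 0.27, 0.194), the piRNA pathway (18, 0.15, 0.279) and interferon-stimulated genes (25, 0.07, 0.439) did not pass. Within them the apoptosis gene Bik (0.68, 0.0401), the polycomb gene Scml2 (0.59, 0.0416) and the early response gene Egr1 (0.75, 0.0331) rose, while Dusp1 (-0.93, 0.0209), Klf2 (-0.77, 0.0338), Klf4 (-0.77, 0.0339) and Dhx58 (-0.61, 0.0357) fell. Adjusted over the list alone, 7 apoptosis genes were higher and 2 lower, 7 immediate early and heat shock genes higher and 3 lower, and 1 interferon-stimulated gene lower. Acat2 (0.53) passed with litter as a block (adjusted p = 0.0476) and not without it (0.0618), and Mov10l1 (0.52, 0.072) did not pass. The 41 genes next to H3f3b on chromosome 11 had a median of 0.11 (adjusted p = 0.595), with 2 higher, Galk1 (0.67, 0.0293) and Sphk1 (0.86, 0.0312), and 2 lower, Myo15b (-1.34, 0.0256) and Foxj1 (-0.58, 0.0425), the same counts adjusted over the list alone. These single calls were all lost without at least 1 array, with highest adjusted p-values from 0.106 for Dusp1 without WT replicate 2 to 0.158 for Bik without KO replicate 2 and Foxj1 without KO replicate 1.

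X-linked genes were higher in KO as a group. Of 429 tested, 318 lay above 0, with a median of 0.21, the highest of any chromosome, while autosomes had medians from 0.01 on chromosome 12 to 0.08 on chromosome 9. Here 17 rose and 2 fell over all probes, or 16 and 2 adjusted over the list alone. Arhgef6 (1.09, adjusted p = 0.00809; another probe -0.28), Ott (0.84, 0.0179), Tab3 (0.81, 0.0276) and Ccdc120 (0.73, 0.0314) had the smallest p, and each lost the call without at least 1 array, at up to 0.0793 for Arhgef6 and 0.101 for Ott without WT replicate 2, and 0.113 for Tab3 and 0.149 for Ccdc120 without KO replicate 1. The group passed with camera (adjusted p = 9.45e-06), also with an estimated correlation (adjusted p = 0.0248). That adjustment covered 2 sets, against 23 for the lists. Before adjustment, camera with an estimated correlation gave p = 0.0124 for X-linked genes. It gave a smaller p of 0.00966 for the elongating spermatid list, whose call did not hold. In the same arrays the round spermatid (median -0.46) and elongating spermatid (-0.26) lists were lower and the Sertoli cell list (0.46) higher. In HET the X-linked median was 0.03 (adjusted p = 0.563). The 9 Y-linked genes had a median of -0.08 in KO (adjusted p = 0.629), or 0.01 without WT replicate 2. Among them Ssty1 (-0.70) passed with litter as a block (adjusted p = 0.0395) and not without it (0.102).

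**Figure D3:**
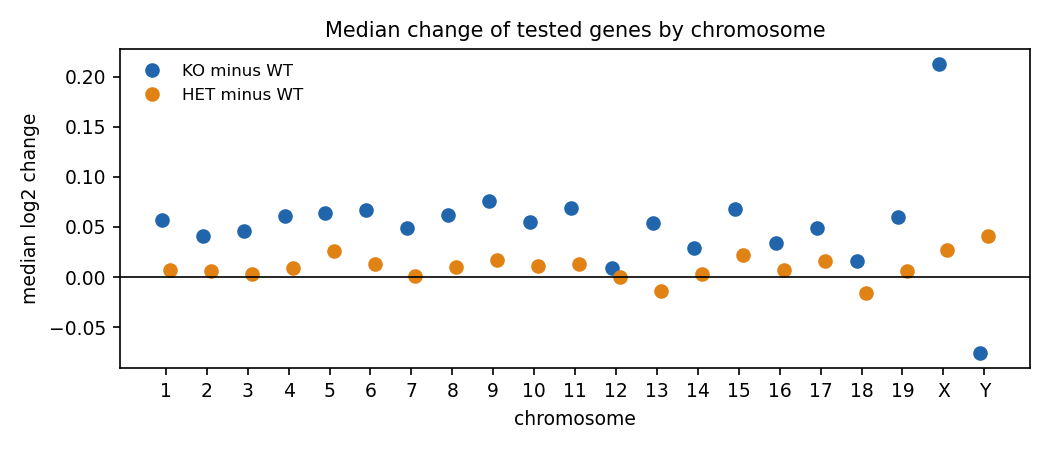
Median log2 change of the tested genes (vertical axis) on each chromosome (horizontal axis) in KO minus WT (blue) and HET minus WT (orange). The X chromosome stood at 0.21 in KO and 0.03 in HET, and the Y point rests on 9 genes.

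The HET mice addressed what losing a single allele changes. With limma, 0 probes passed in HET against WT, with 1740 at an unadjusted p under 0.05 against 1102 by chance and a lowest adjusted p of 0.222; other settings called from 0 to 17. The smallest p-values belonged, on the higher side, to BC057079 (0.94), Dctn1 (1.34), Prpf8 (1.15), Gpd1 (0.77, at least 1.58-fold, as WT was not above background) and 2 gene models, and on the lower side to Ston1 (-1.08), Prrt4 (-0.94), Pmpca (-0.98), Fxyd2 (-0.95), Sfmbt2 (-0.91) and Adam4 (-0.89). Their adjusted p-values ran from 0.222 to 0.484. The H3 genes Hist2h3c1 (-0.78, SE 0.167), Hist2h3b (-0.67, SE 0.154) and Hist1h3h (-0.37, SE 0.134) did not pass either (adjusted p = 0.516, 0.529 and 0.586). Adjusted over the list alone, 2 replication-coupled histone genes and H3f3b in the H3.3 list were lower in HET. Across probes, which are not independent replicates, Pearson's r between HET and WT arrays was 0.9927, 0.9922, 0.9919 and 0.9912, so 3 of the 4 pairs lay below the replicate pairs of WT (0.9926), HET (0.9932) and KO (0.9929). Among the lists, round spermatid genes passed downward (median -0.10, 33 of 38 below 0, adjusted p = 0.0171; adjusted p = 0.636 with an estimated correlation), with 0 genes passing in limma over all probes or adjusted over the list alone. Hook1 (-0.90, adjusted p = 0.529) had the smallest p in it. This call was lost without WT replicate 2 (median -0.002, 0.258) and without HET replicate 1 (-0.02, 0.438). The Sertoli cell list had a median of 0.11 (adjusted p = 0.0759) and the Leydig cell list -0.10 (0.0904).

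**Figure D4:**
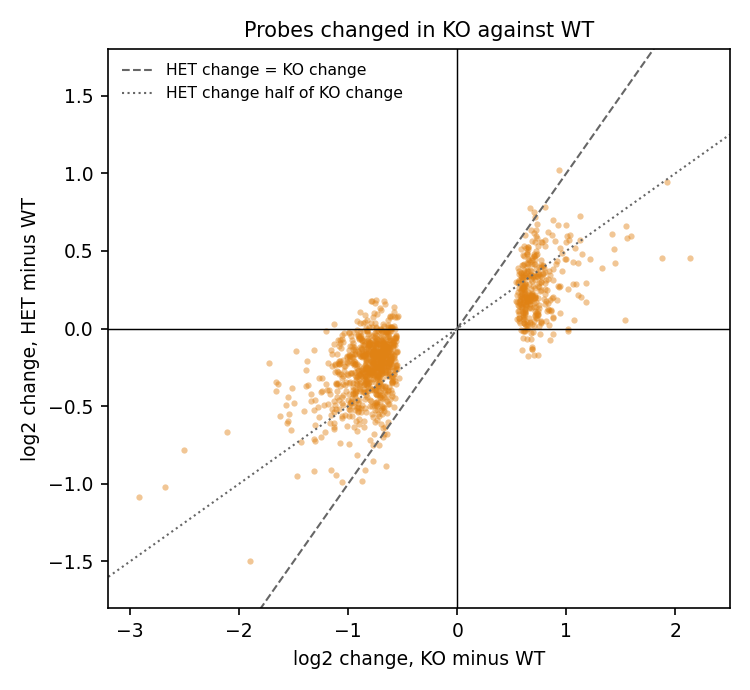
Log2 change in HET minus WT (vertical axis) against KO minus WT (horizontal axis) for 1173 of the 1174 probes that passed in KO against WT, with 1 probe (H3f3b) outside the range; lines mark equal changes and a HET change at 50% of the KO change. Of the 1174, 93.3% had a HET mean between those of WT and KO, against 55.8% with a simulated unchanged HET group. The simulation kept the observed KO changes in full and may understate the part built in by shared WT arrays.

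Of the 1174 probes that passed in KO against WT, 94.3% had a HET change of the same sign, and the HET mean lay between the WT and KO means for 1095 (93.3%). Because both comparisons use the same WT arrays, part of this is built in: simulated unchanged HET groups gave 56.1% (52.9% to 59.2% over 50 simulations) for the sign and 55.8% (52.3% to 58.8%) for a HET mean in between. The simulations gave the 1174 probes their observed KO change in full and all other probes none, with noise independent between probes. They may therefore understate the part that is built in. The median ratio of the HET to the KO change was 0.312 (simulated 0.0286). Over all probes the covariance of the changes was 0.0397 against 0.0141 simulated, and their correlation was 0.563 against 0.322.

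The comparison of KO with HET asked what losing the remaining allele changes. Hsd3b4 (1.68, SE 0.173, adjusted p = 0.0134), Vmn1r181 (1.49, 0.0339), Lor (1.42, 0.0337) and BC057079 (0.98, 0.0497) rose, and Akr1c19 (0.92, 0.0646) and Six2 (0.87, 0.068) did not pass. After H3f3b, Ston1 fell by 1.84 (SE 0.131, adjusted p = 0.00129), Hist2h3c1 by 1.72 (SE 0.167, adjusted p = 0.00972) and Hist2h3b by 1.44 (SE 0.154, adjusted p = 0.0157), followed by Hs3st3b1 (1.31), Art1 (1.28), Fam50b (1.17), Rundc3a (1.08), Hspbap1 (1.06) and 3 genes with only clone or model names, for which adjusted p lay between 0.0297 and 0.0498. In all 18 probes passed, 4 higher and 14 lower, with 3815 at an unadjusted p under 0.05, and all 18 also passed in KO against WT in the same direction. Independent lists would share 0.521 lower and 0.0642 higher probes, a value that leaves out the shared KO arrays, and groups simulated without any effect shared at most 1, a value that leaves out the effects in KO. Neither says what an unchanged HET group would share, and part of the overlap may come from the KO arrays used by both comparisons. With litter as a block 8 probes passed (1 higher, 7 lower; 7 of the 18), and Vmn1r181, Lor, BC057079, Fam50b, Rundc3a, Hspbap1 and the 3 model names (each 0.0588) and Art1 (0.055) no longer did. Other scalings gave 361 higher and 548 lower without background correction, 367 and 643 with normexp with offset 50, 161 and 92 with median scaling (median of all probes 0.101), and 1027 and 629 with the series matrix values. The count fell to 10 without WT replicate 1, 8 without WT replicate 2, 8 without HET replicate 1, 4 without HET replicate 2, 3 without KO replicate 1 and 2 without KO replicate 2. Of the genes named, H3f3b and Ston1 passed in each of these 6 fits. Hist2h3c1, Hist2h3b and Hsd3b4 lost the call in 3 of the fits, and Art1 and Fam50b in 5. Vmn1r181, Lor, BC057079, Hs3st3b1, Hspbap1, Rundc3a, 4930455F16Rik and 1700096P03Rik lost the call in all 6.

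Of the 23 lists, 6 passed in KO against HET. Round spermatid genes (median -0.36, 32 of 38 below 0, adjusted p = 8.28e-08), elongating spermatid genes (-0.20, 4.59e-06) and replication-coupled histone genes (-0.14, 2.82e-04) were lower. Sertoli cell genes (0.34, 32 of 35 above 0, 1.3e-07), Leydig cell genes (0.48, 19 of 23 above 0, 4.59e-06) and cholesterol biosynthesis genes (0.27, 0.0224) were higher. With an estimated correlation 0 of these 6 calls held in camera, at adjusted p = 0.234 to 0.313. Fry kept the elongating spermatid (adjusted p = 0.0201), histone (0.0201) and Sertoli cell lists (0.0488). It lost the round spermatid (0.0611), Leydig cell (0.0894) and cholesterol lists (0.0894). Over all probes, 2 histone genes fell and 0 members of the other 5 lists passed in limma; adjusted over the list alone, 9 round spermatid and 8 histone genes fell, 12 Sertoli cell and 13 Leydig cell genes rose, and 0 elongating spermatid or cholesterol genes changed. Catsper1 (-0.90, adjusted p = 0.075), the transferrin gene Trf (0.82, 0.083), Cyp17a1 (0.86, 0.103), Spatc1 (-0.54, 0.123) and Acat2 (0.49, 0.152) had the smallest p of their lists. The cholesterol list lost its call without HET replicate 1 (0.178) and without KO replicate 1 (0.0963). X-linked genes were higher again, with a median of 0.16 and 314 of 429 above 0 (camera adjusted p = 3.8e-06). With an estimated correlation the camera adjusted p was 0.0221 over 2 sets. Before adjustment this camera p was 0.0111, against 0.0102 for the elongating spermatid list, whose call did not hold.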

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

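Counts moved between settings, and so did the balance of higher and lower probes. In KO against WT, 1174 probes became 2929 with no background correction, 3001 with normexp with offset 50, 1762 with median scaling, 4224 with the series matrix values, 528 with no filter, 2104 with a detection p under 0.01 on all 6 arrays, 774 with only the 2 groups compared, 2908 with an intensity trend and robust variance, and 22 to 795 with 1 array left out; 7 lists became 11 with no filter, 0 with an estimated correlation and 12 with fry. In HET against WT, 0 probes became 2 with no background correction, 8 with normexp with offset 50, 6 with median scaling, 17 with the series matrix values, 7 with trend and robust variance and 0 to 1 with 1 array left out. There, 1 list became 5 with no background correction, 5 with normexp with offset 50, 8 with the series matrix values, 6 with no filter, 0 with an estimated correlation and 0 to 5 with 1 array left out. In KO against HET, 18 probes became 909, 1010, 253 and 1656 with the first 4 settings named, 2 with no filter, 231 with the strict filter, 8 with litter as a block, 10 with only the 2 groups compared, 1054 with trend and robust variance and 2 to 10 with 1 array left out, and 6 lists became 0 with an estimated correlation. H3f3b in HET passed at -0.714 with normexp with offset 50 and -0.756 with the series matrix values. In KO against WT, fry kept the round spermatid (adjusted p = 0.0209), elongating spermatid (0.00856) and Sertoli cell lists (0.0205). It also kept the replication-coupled histone (0.00856) and proliferation lists (0.033), and lost the Leydig cell (0.105) and erythrocyte lists (0.0841). In HET against WT, fry lost the round spermatid list (adjusted p = 0.492).

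Of the 76 results for named genes that passed, none turned its sign, and the other passing probes were not followed one by one. Genes named by size were chosen for arrays that did not overlap between groups. Their signs therefore could not turn within litters and hardly could with 1 array left out. Among small changes that did not pass, H3f3a in KO turned to -0.00578 with cyclic loess, -0.0605 with median scaling, -0.0353 with the series matrix values and -0.197 within litter 1, on 2 probes, and with 1 array left out to -0.0753 and -0.0187 on 1 probe (-0.0753 to 0.28) and to 0.0234 and 0.0588 on another (-0.21 to 0.0588). H3f3a in HET turned to 0 within litter 1, 0.2 and -0.0116 within litter 2, and 0.0974 and 0.0214 with 1 array left out (-0.257 to 0.0974). Tnp1 turned to 0.0633 and Prm1 to 0.203 with cyclic loess, Prm1 to 0.0406 without KO replicate 2 (-0.145 to 0.0406 with 1 array left out) and 0 within litter 1, and Bpgm to 0.0461 within litter 1. Slide as a block was not run, as the columns show no slide. Litter as a block changed no call of a named gene or fixed list other than those printed, and 1470 probes passed with it in KO against WT, 1133 of them shared. For results that did not hold or were reversed, the cause was not tested.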

Other observations

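The gene families, the rule that formed them and the 7 tests of explanations of this part were chosen only after the result was seen, while the lists and the 5 other scalings that they use were planned. Families of genes that share a symbol stem were compared between KO and WT. All 10 tested Speer genes, a rodent family expressed in spermatids, lay below 0 (median -0.50, camera adjusted p = 6.7e-04; adjusted p = 0.815 with an estimated correlation, as for each of the 8 that passed), with Speer6-ps1 (-0.66, limma adjusted p = 0.0352), Speer9-ps1 (-0.69, 0.0419) and Speer4f1 (-0.67, 0.0492) lower. The Ttll family, tubulin ligase-like enzymes that modify axonemal tubulin, was lower as well (12 genes, median -0.38, adjusted p = 0.0213), with Ttll8 (-0.87, 0.0324), Ttll3 (-1.05, 0.0401) and Ttll9 (-0.61, 0.0498) passing, as was Spata (26 genes, -0.30, 0.00364; 8 of them are in the lists above). Higher were the aldo-keto reductases (9 genes, 0.48, 0.0303; Akr1cl 0.73, 0.042 and Akr1b8 0.60, 0.0492, beside Akr1c19), Cdk (20 genes, 0.29, 0.0211; Cdk16 0.63, 0.0364), the sorting nexins (25 genes, 0.32, 0.0308; 2 members higher and Snx3 lower, -0.61, 0.0496) and Atp (68 genes, 0.21, 0.0308; 3 members higher and Atp6v1e2 lower, -0.97, 0.0183). The ribosomal Rpl family (46 genes, 0.16, 0.0466) was borderline: under a first version of the family rule, with 201 families, it did not pass (0.0501), while the other 7 did. In all 8 of 187 families passed, 0 of them with an estimated correlation, and 9 with litter as a block, which added Lrrc (39 genes, -0.14, adjusted p = 0.0413 with the block and 0.0675 without). The signs of the 8 held in 5 other scalings, and Speer paralogs are so alike that their probes may read the same RNA, which was not analysed here; the same arrays showed the Sertoli cell list 0.354 or more above 0 in every scaling.

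Lower spermatid and higher Sertoli cell genes could follow from a lower share of spermatid RNA alone, in which case all other cell types should rise alike. Among genes with a mean log2 value of at least 7, Sertoli cell genes rose more than leukocyte and endothelial genes together, by 0.324. The difference was 0.372 and 0.357 within the litters (23 against 15 genes). The permutation p was 0.0062, but it shuffled genes, not animals, and treated genes that move together as independent. The lists were also set against each other after their medians were known, at 0.461 for Sertoli cell, 0.18 for leukocyte and -0.00305 for endothelial genes. The permutation p leaves out that choice, so the difference does not decide against the share alone. The test was first run against endothelial genes alone (0.591, 4 genes, permutation p = 4e-04), and the comparator was widened after that value was seen. Leydig (-0.0553, permutation p = 0.613) and myoid genes (0.0842, permutation p = 0.244) stayed close to Sertoli cell genes, as did spermatogonial genes (0.104, 5 genes, permutation p = 0.315), which goes with the share. Over all tested members the medians were 0.326 for Leydig, 0.158 for myoid and 0.144 for spermatogonial genes, against 0.461 for Sertoli cell genes. Spermatocyte genes (0.416 below Sertoli cell genes, 25 genes, permutation p = 1e-04) and erythrocyte genes (0.973 below, 4 genes, permutation p = 8e-04) lay further off, but neither decides. Meig1 is in both the spermatocyte and the elongating spermatid list, and expression of spermatocyte genes in spermatids was not analysed. Erythrocytes can be carried along by dissection, and their 4 genes had medians of -0.808 in litter 1 and -0.114 in litter 2. Neither list depended on scaling: over 5 other background corrections and normalizations the median nearest 0 was -0.422 for round spermatid genes and 0.354 for Sertoli cell genes. A lower spermatid share, alone or together with changes in other cells, remains open.

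The decrease of replication-coupled histone genes might come from H3f3b RNA binding to H3 probes in WT. Other probes of Hist2h3c1 differed by only -0.2 and 0.14 between KO and WT. Another Hist1h3h probe also moved less, as given above, so each of these decreases rests on a single probe. The tests could not tell: the 36 genes of the list other than H3 had a median of -0.083, which 3.12% of 10000 random lists of matched intensity reached, with 5 of them passing as lower, and Hist2h3c1 lost 49.9% of its WT to KO drop in HET (60.8% and 39.3% within the litters), Hist2h3b 47.8% and Hist1h3h 43.2%, against 39.7% for H3f3b. The H2B genes alone (11 genes, -0.453, with -0.449 and -0.611 within the litters) were looked at first. Of 10000 matched random lists, 0.11% reached their median. They had been picked among the histone classes for their decrease, which that share leaves out, and the 13 H2A genes lay at 0.196. The H2B genes therefore do not decide the question, and probe sequences would be needed. Fewer cells in S phase would lower other S-phase genes too. Of these, 15 had a median of 0.131 (9 above 0), against -0.232 for all 45 histone genes of the list. The permutation p over genes was 0.018, in a comparison first made with the H3 and H2B genes alone. This cannot exclude fewer S-phase cells: the list was known to be lower and includes the H3 genes whose probes are in question. The S-phase genes were also not set against the rise of other non-spermatid lists. Which forms of histone RNA these probes read was not analysed either. An effect of genotype and a loss of histone RNA carried by spermatids were not tested.

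HET values between WT and KO could arise because both comparisons use the same WT arrays. With no array in common, the KO and HET changes still correlated across probes, at 0.174 with KO from litter 1 and 0.257 with KO from litter 2. Simulations with an unchanged HET group gave at most 0.0168 for either pairing, and the 2 values differ by 0.0825, so shared WT arrays alone do not account for them; this bound was drawn after the values were seen. The simulations leave out deviations that many probes of an array share, whose part was not tested. A partial effect of 1 lost allele is consistent with the lower value of 0.174, and 2 mice per group cannot settle its size.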
